A study of Felis catus with 15 samples.

How the data were processed

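Serum of 7 diabetic and 8 healthy cats was profiled, 1 array per cat. Per the labels' protocols, blood was clotted and centrifuged, total RNA was extracted with a column kit made for serum, and miRNA was labelled with Cy3. Per the file headers, the arrays were mouse miRNA designs read with Agilent Feature Extraction 10.7.3.1. The deposited files hold spot intensity on a linear scale after the scanner software's background subtraction, which can be negative. Per the file headers, flags mark spots that are well above background, outliers or saturated, and no spot was saturated. The authors' value table also holds intensity: over 45324 features its values differed by 0 from the processed signal of the same array, so it is linear and unscaled. Neither scaling between arrays nor the authors' test is given in the sources used here.

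Each array carried 2754 probes for 1079 miRNA names, with 10 to 40 spots per probe. Control spots and outlier spots were left out. A probe was called detected on an array when most of its remaining spots were well above background, which held for 14.9% of probe and array pairs. Each array was therefore scaled by its 75th percentile over the 193 probes detected on all 15 arrays. Spots of one probe were averaged, a floor of 9.68 (3.28 on the log2 scale) was set, and log2 was taken. The floor was the median over arrays of the 5th percentile of scaled signal among spots well above background. A floored signal understates the difference of a dim miRNA. Probes detected on at least 7 of the 15 arrays were tested, which gave 395 probes and 198 miRNAs. A miRNA was represented by its brightest probe. No named miRNA that was tested lay below background on every array of a group, so no bound was given. Bounds were not sought for the other tested miRNAs. Of these, miR-714 and miR-3065* lay at the floor on every healthy array, so their differences depend on the floor.

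Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes, Benjamini-Hochberg adjustment and a threshold of 0.05. Lists were tested with camera at its preset correlation. Camera with an estimated correlation, and fry, which tests whether a list's members move on balance in one direction, were alternatives. Of 15 lists fixed by name, 121 of 139 member entries matched a name on the array, and 7 lists had at least 3 tested members. Members with 2 candidate arms on the array were left unmatched. Single measures were compared by two-sided exact permutation tests over all splits of the 15 arrays, or over the splits of 1 slide. The cats are separate animals, so the p-values of single miRNAs and single measures reflect the spread between cats. Values set to the floor hide that spread. For miRNAs dim in healthy cats, such as miR-122, miR-193b and miR-375, the SE and p-value can therefore be too small. Camera compares a list's members with the other miRNAs, and its low preset correlation treats members as almost independent. The estimated correlation was 0.772 for the erythrocyte list, 0.735 for the liver list and 0.452 for the list reported in human type 2 diabetes. Camera's p-values at the preset can therefore be too small.

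Named miRNAs were those that passed, the 8 of lowest p in each direction among those that did not, the 3 tested members of lowest p of each list, the 5 brightest, and 8 fixed names. This rule, the tests, the lists and most alternatives were set before the data were examined. Scaling by hybridisation spike-ins and the software's total signal per miRNA were chosen after seeing the data. The other alternatives covered the background, scaling, filter, floor, slide, replicate number, variance model, array weights, haemolysis index, the authors' values and leaving out each array in turn. The intended normexp background used mean signals, and the median signal with the median background was used in its place because the files hold no mean signal column.

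The fit was tested on simulated data with 198 miRNAs and the real group sizes, in 100 simulations with 7 changed miRNAs at each size. It recovered 44.3% of changes of 1 on the log2 scale, 84.0% of changes of 2 and 98.4% of changes of 4, with 5.2% false calls on average. Of 100 simulations with no change, 3 gave a call. The simulated miRNAs varied independently of each other and had no floor. Real miRNAs correlated within lists and many values lay at the floor, so these rates may not hold for the real data. Slide could be tested as a batch, because each of the 2 slides held both groups. Arrays correlated between 0.593 and 0.967 with each other, so none was a copy of another.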

Results

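MicroRNAs (miRNAs), short non-coding RNAs that repress messenger RNAs, were measured in serum of client-owned adult cats on 1-colour Agilent mouse miRNA arrays, with 1 array per cat. The 15 arrays came from 7 cats with diabetes and 8 healthy cats. The form of diabetes is not given in the sources used here. A further diabetic sample, from a leaking hybridisation chamber, was left out by the submitters and is not analysed here. The probes were designed for mouse miRNAs, so a signal stands for cat RNA that bound a mouse probe, and each miRNA has the name of that probe. Genomic positions of the miRNAs are not given in the sources used here. Of the 43160 non-control spots, between 4517 (healthy 4) and 11391 (diabetic 5) were well above background, or 10.5% to 26.4%. The number of arrays limits the precision of each value.

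The comparison asked which serum miRNAs differed between diabetic and healthy cats. Of 198 miRNAs tested, 5 rose and 1 fell in diabetic cats. The largest rise was that of miR-122, the most abundant miRNA of hepatocytes. Its scaled signal was 9.17 ± 2.73 on the log2 scale (SD, n = 7) in diabetic cats and 3.61 ± 0.61 (SD, n = 8) in healthy cats. The log2 difference was 5.56 (SE 0.909) (limma adjusted p = 0.00325). All 7 diabetic cats were above the highest healthy cat, at 5.17 or more against 4.76 or less. Among the 6 miRNAs that passed, miR-122 was the 1 whose groups did not overlap, a separation that chance gives in 0.0311% of splits for a single miRNA. Because miR-122 was detected in 3 of 8 healthy cats, the size of its rise depends on the floor of 3.28 log2 given to dim signals. It was 6.01 with a lower floor. Over all alternatives it ranged from 3.22 (normexp background) to 6.22 (total signal per miRNA).

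miR-193b, which is expressed in fat and liver, rose by 3.40 on the log2 scale (SE 0.688, adjusted p = 0.0119). It was detected in 7 of 7 diabetic and 4 of 8 healthy cats, so its size depends on the floor too, at 3.84 with a lower floor. Its log2 difference ranged from 1.48 (normexp background) to 4.12 (total signal per miRNA) over all alternatives. miR-378b, of the family of miR-378, which lies within a gene for a coactivator of energy metabolism, rose by 2.59 (SE 0.576, adjusted p = 0.0194), a fold of 6.00. miR-375, enriched in pancreatic islets where it restrains insulin secretion, rose by 1.27 (SE 0.328, adjusted p = 0.0471). It was also detected in 7 of 7 diabetic and 4 of 8 healthy cats, and its size depends on the floor, at 1.67 with a lower floor. Over all alternatives it ranged from 0.20 (normexp background) to 1.90 (total signal per miRNA). miR-139-3p rose by 1.11 (SE 0.228, adjusted p = 0.0119), from 8.22 ± 0.46 (SD, n = 8) to 9.33 ± 0.34 (SD, n = 7). The miRNA that fell was miR-1892, from 8.02 ± 0.92 (SD, n = 8) to 6.61 ± 0.39 (SD, n = 7). It fell by 1.41 on the log2 scale (SE 0.362, adjusted p = 0.0471). For each of the 6, all 7 diabetic cats lay on the same side of the healthy mean. The 6 were picked for their difference on these same arrays, so this is not further evidence. No miRNA had probes that differed in opposite directions at an unadjusted p under 0.05, though 7 of the 198, none of them among the 6, had probes of opposite sign. The sequences of miR-378 and miR-378b are close, so their probes can share RNA.

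**Figure D1:**
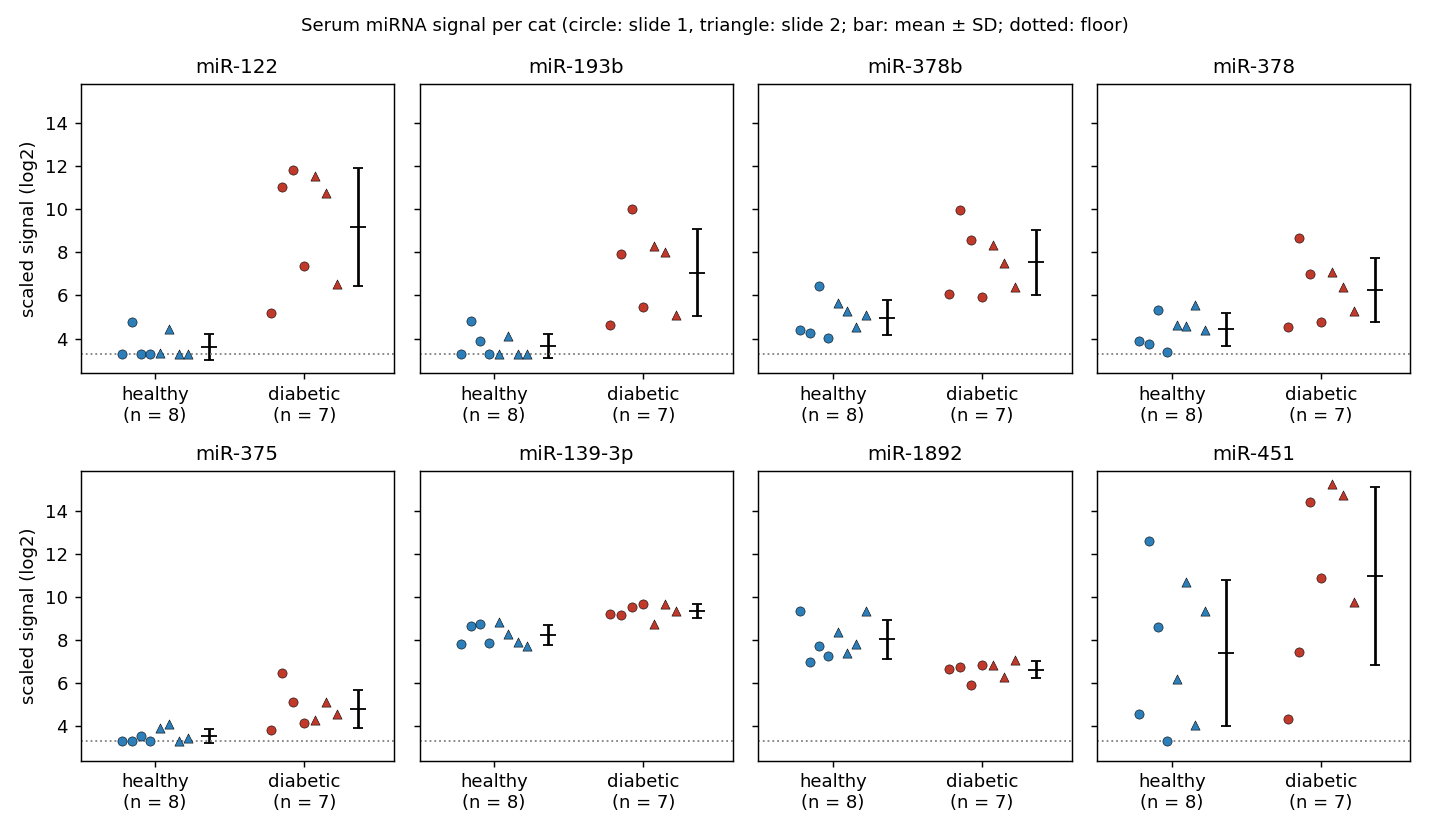
Scaled signal (log2, vertical axis) of 8 miRNAs in each healthy (blue) and diabetic (red) cat, with circles for slide 1, triangles for slide 2, bars for the mean and SD, and a dotted line at the floor of 3.28. miR-122 lies at 5.17 or more in all 7 diabetic cats and at 4.76 or less in all 8 healthy cats, while miR-378 and miR-451, which did not pass the test, overlap between the groups.

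Within slide 1 the log2 difference was 5.20 for miR-122, 3.18 for miR-193b, 2.85 for miR-378b, 1.53 for miR-375, 1.14 for miR-139-3p and −1.30 for miR-1892. Within slide 2 it was 6.04, 3.64, 2.29, 0.97, 1.06 and −1.49 in the same order. None of the 6 passed within a single slide, at adjusted p = 0.538 for each on slide 1 and 0.148 to 0.275 on slide 2. With the slide as a block, miR-122, miR-193b, miR-378b and miR-139-3p passed, and miR-375 and miR-1892 did not (adjusted p = 0.0575 for both). Without the detection filter no miRNA passed, and of the fits that left out 1 of the 15 arrays, 4 called miR-375 and 3 called miR-1892. On both slides the diabetic arrays lay in row 1 and the healthy arrays in row 2, so slide row and group cannot be told apart.

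At the level of single probes, 14 of 395 passed, 11 higher and 3 lower in diabetic cats, and 94 had an unadjusted p under 0.05. The 14 probes carried 10 names, the 6 above with miR-5105, miR-339-3p, miR-712 and miR-1894-3p. Of the 198 miRNAs, 128 were higher and 70 lower in diabetic cats, and 44 had an unadjusted p under 0.05, 32 higher and 12 lower. The higher miRNAs of lowest p that did not pass were miR-5105 (log2 difference 0.82, adjusted p = 0.0526), miR-378 (1.81), miR-29a (1.85), miR-339-3p (0.79), miR-34a (1.48), miR-2861 (0.91), miR-423-5p (0.64) and miR-22 (2.06), the last 7 at adjusted p = 0.109. The lower ones that did not pass were miR-1894-3p (−0.81, adjusted p = 0.0797), miR-483 (−1.04), miR-1896 (−0.62), miR-3474 (−1.29), miR-1971 (−0.60), miR-1907 (−0.59), miR-652* (−0.73) and miR-598* (−0.92), the last 7 at adjusted p = 0.109 to 0.129. The 5 brightest miRNAs were miR-5126 (log2 difference 0.51), miR-5100 (−0.05), miR-709 (0.43), miR-3960 (0.57) and miR-1224 (−0.25), and none of these passed.

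The median log2 difference over the 198 miRNAs was 0.21, and 64.6% were higher in diabetic cats. This median lay between −0.17 with quantile normalization and 0.42 with spike-in scaling, so the differences are relative to the scaling. The share that was higher was 40.4% with quantile normalization, 46.0% with the percentile over all probes, 49.5% with normexp background, 51.0% with the haemolysis covariate and 72.7% with spike-in scaling, so whether most miRNAs were higher depends on the processing. Against 5 higher and 1 lower, quantile normalization called 3 higher (miR-122, miR-193b and miR-378b) and 2 lower (miR-1892 and miR-1894-3p), and spike-in scaling called 2 higher (miR-122 and miR-193b) and 0 lower. With normexp background correction miR-122 rose by 3.22 while 3 of the 5 rises did not pass. These were miR-193b (1.48, adjusted p = 0.0871), miR-378b (1.44, adjusted p = 0.0742) and miR-375, whose difference was 0.20 (adjusted p = 0.886). This correction adds an offset of 50 to the signal, which by itself shrinks the log2 differences of dim miRNAs. The signal of miR-375 was dim, at 4.78 on the log2 scale in diabetic cats in the main fit.

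Among 7 preset lists with at least 3 tested members, 3 were shifted upwards against the other miRNAs by limma's camera test with a preset correlation. All 11 tested members of the list reported in the blood of people with type 2 diabetes were higher, with a median log2 difference of 1.31 (camera adjusted p = 0.00797, and adjusted p = 0.522 with an estimated correlation). Of these 1, miR-375, passed on its own. Others were miR-34a (1.48) and miR-29a (1.85), and 3 members passed when adjusted over the list alone. Of the 11 members, 8 also stood in another list. The direction reported in people was not used, so the 11 higher members do not show the same change as in people. In the liver list all 3 tested members were higher, with a median of 1.97 (camera adjusted p = 0.0394, and adjusted p = 0.522 with an estimated correlation). Of these miR-122 passed, and miR-192 (1.97) and miR-101a (0.73) did not. Adjusted over the list alone, 1 passed. The median of the erythrocyte list was 1.63 (camera adjusted p = 0.0394, and adjusted p = 0.522 with an estimated correlation). All 6 of its tested members were higher and none passed, also when adjusted over the list alone. The red cell miRNA miR-451 differed by 3.57 on the log2 scale, miR-16 by 2.14 and miR-92a by 1.66. Of 100 splits of the 15 arrays, 18 called 3 or more lists. The fry test passed the liver list (adjusted p = 0.0472) and the diabetes list (adjusted p = 0.0480) and not the erythrocyte list (adjusted p = 0.0853). The median of the erythrocyte list was 1.33 within slide 1 (adjusted p = 0.195) and 2.20 within slide 2 (adjusted p = 0.0156). That of the liver list was 1.39 (adjusted p = 0.195) and 2.71 (adjusted p = 0.0168), and that of the diabetes list 1.13 (adjusted p = 0.0131) and 1.54 (adjusted p = 0.0168). With the slide as a block the 3 lists passed, with medians of 1.65, 1.999 and 1.34. The fits within slides and with the slide as a block used camera's preset correlation alone.

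The other lists did not pass. All 6 tested members of the miR-29 and miR-30 families were higher, among them miR-29a (1.85), miR-29c (1.25) and miR-29b (1.31), with a median of 1.09 (camera adjusted p = 0.0625), and 2 passed when adjusted over the list alone. All 4 tested members of the platelet list were higher, with a median of 0.83 (adjusted p = 0.272) and miR-21 (1.65), miR-24 (1.09) and miR-484 (0.44) of lowest p. All 5 leukocyte members were higher, with a median of 0.81 (adjusted p = 0.451), among them miR-223 (1.94), miR-146a (1.02) and miR-342-3p (0.81). Of the 5 tested adipose and metabolic miRNAs, 3 were higher and 2 lower (median 0.90, adjusted p = 0.501), with miR-378 (1.81), miR-107 (1.71) and miR-27a (0.90) of lowest p, and 1 passed when adjusted over the list alone. Lists with under 3 tested members had no set test. They were the let-7 family (let-7b at 1.28, let-7i at 1.08, of which 2 passed when adjusted over the list alone), the nervous system (miR-128 at 1.23, miR-138 at 0.98, of which 1 passed so), the miR-17 family (miR-19b at 1.51, miR-106b at 0.63, of which 0 passed so), endothelium (miR-99a at 0.87, miR-10b at 0.77, of which 0 passed so), muscle (miR-133b at 0.52, which did not pass so) and islet (miR-375, which passed). No epithelial miRNA was tested. The list remembered from the publication on these cats had 1 tested member, miR-193b, which passed. That list was chosen on these samples, so its count is not independent evidence. Its other members were not tested, as miR-122* was detected on 0 and miR-483* on 6 of the 15 arrays. With the software's total signal per miRNA, an alternative chosen after seeing the data that tested 244 miRNAs, miR-483* was tested and was higher by 1.82 (SE 0.354, adjusted p = 0.0105).

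**Figure D2:**
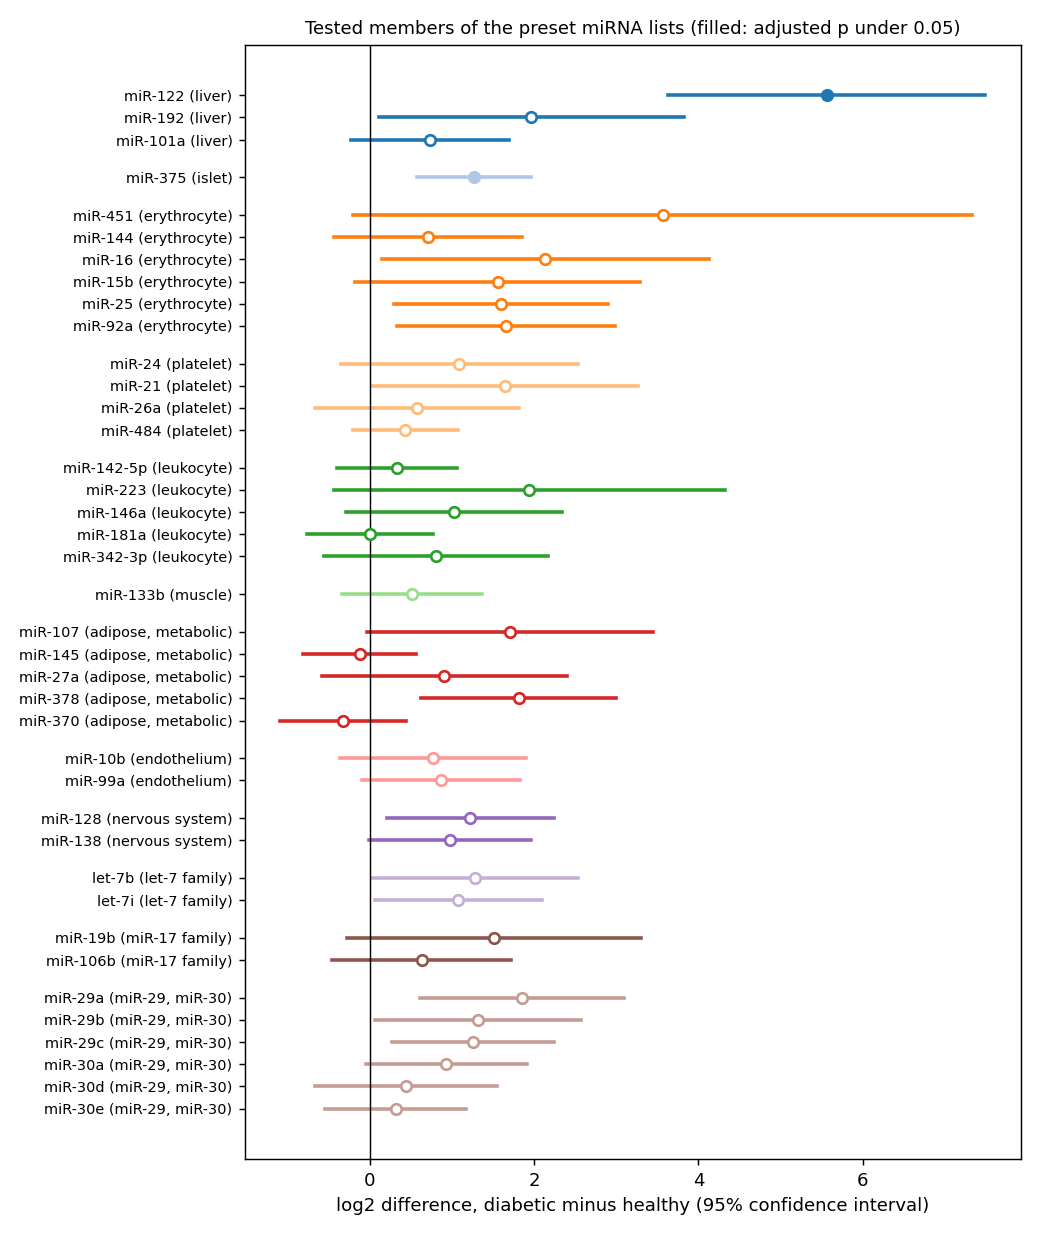
Log2 difference, diabetic minus healthy (horizontal axis), of the tested members of 12 preset lists, with the 95% confidence interval as a line and a filled circle for adjusted p under 0.05. Most members lie to the right of 0, and the filled circles are miR-122 at 5.56 and miR-375 at 1.27.

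Serum quality was compared through the haemolysis index, the log2 signal of miR-451 minus that of miR-23a, which rises when red cells break. It was 2.83 ± 2.30 (SD, n = 7) in diabetic cats and 1.46 ± 1.40 (SD, n = 8) in healthy cats, a difference of 1.38 (two-sided exact permutation p = 0.177). The difference was 0.16 within slide 1 (exact p = 0.857) and 2.98 within slide 2 (exact p = 0.0286, the smallest that this slide's 7 arrays allow). Without diabetic 1 it was 2.09 (exact p = 0.0193). miR-451 itself differed by 3.57 (exact permutation p = 0.0892), and miR-23a, the reference of the index, by 2.19 (exact permutation p = 0.0702). In healthy 4 both were at the floor, so its index of 0 is not a measurement. With the index as a covariate in the fit, miR-122 rose by 4.65 (adjusted p = 0.00363), and miR-193b and miR-139-3p passed (adjusted p = 0.0352 for both). miR-378b, miR-375 and miR-1892 then did not pass, nor did the liver (median 1.16, adjusted p = 0.0621) and erythrocyte lists (1.00, adjusted p = 0.113). The diabetes list passed with the covariate at camera's preset correlation, with a median of 0.63 (adjusted p = 0.0233). With an estimated correlation and no covariate it did not pass (adjusted p = 0.522), so this does not show that the list outlasts the correction.

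Detected probes numbered 447 ± 119 (SD, n = 7) in diabetic cats and 378 ± 83.2 (SD, n = 8) in healthy cats, a difference of 69.5 that lay within the spread (exact permutation p = 0.211). It was 18.5 within slide 1 (exact p = 0.714) and 139 within slide 2 (exact p = 0.114). The array of healthy 4 stood apart by its labelling spike-in, at 1.55 on the log10 scale against 2.83 or more in the other healthy cats. Without healthy 4, 9 probes, 5 miRNAs and 2 lists passed. The call of miR-375 (adjusted p = 0.101) and that of the erythrocyte list (adjusted p = 0.0636) ended.

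**Figure D3:**
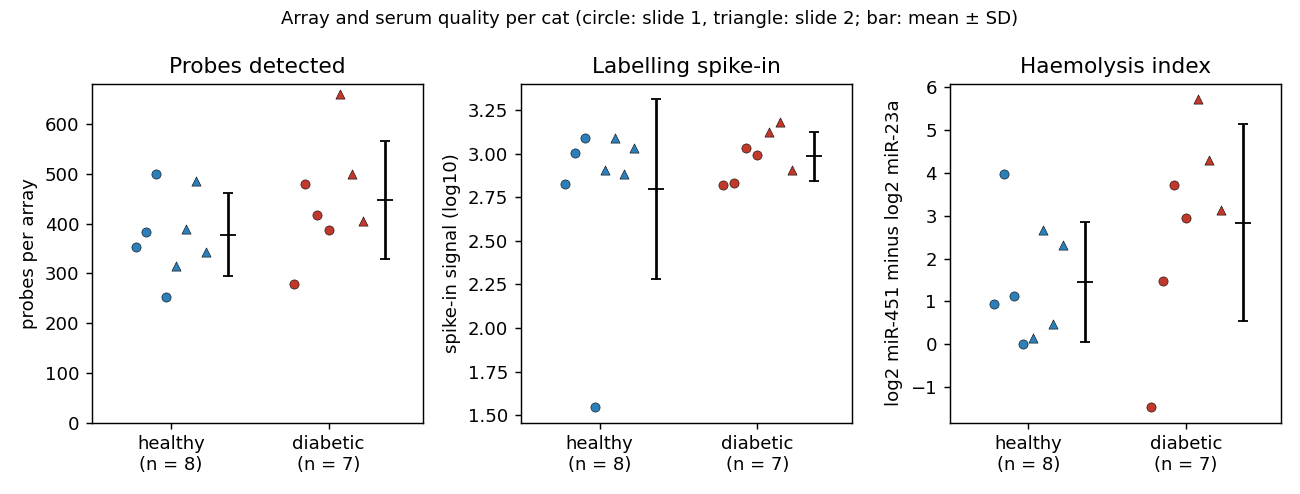
Probes detected per array, labelling spike-in signal (log10) and haemolysis index (log2) in each healthy (blue) and diabetic (red) cat, with circles for slide 1, triangles for slide 2 and bars for the mean and SD. Both groups overlap in each measure, and healthy 4 lies apart at a spike-in signal of 1.55.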

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

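The test of detection by chance and that of the red cell list were chosen only after the result was seen. Among 114 groups of values, 16 had 1 array far from the rest of its group. Chance gives this in about 5% of groups only where values are normal and not tied. Many values were tied at the floor, such as let-7b in all healthy cats but healthy 2. The groups also shared arrays, so 16 of 114 cannot be set against 5%. Healthy 2 stood above the other healthy cats for miR-16 (6.51 on the log2 scale, next 4.73), let-7i (4.53), let-7b (5.09), miR-107 (5.09), miR-99a (4.42), miR-101a (4.45) and miR-10b (5.57). Healthy 4 stood below the other healthy cats for miR-29a (3.28, at the floor), miR-92a (5.84), miR-709 (11.62), the labelling spike-in (1.55 on the log10 scale) and the hybridisation spike-in (3.75 on the log10 scale). Diabetic 3 was high for miR-423-5p (8.25), diabetic 4 for miR-1907 (3.77), healthy 7 for miR-598* (7.17) and healthy 6 for miR-484 (4.77).

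Among miRNAs detected on too few arrays to be tested, 83 appeared in 1 group alone, 57 of them in diabetic and 26 in healthy cats. The 8 found in at least 4 cats of that group are named here. miR-129-2-3p was detected in 5 diabetic cats and 0 healthy ones, and miR-129-1-3p, miR-130a, miR-148a, miR-193 and miR-505-3p in 4 and 0. miR-351* was detected in 0 diabetic cats and 5 healthy ones, and miR-3071 in 0 and 4. None passed Fisher's exact test after adjustment over the 161 detected but untested miRNAs (lowest adjusted p = 0.539), and 12 had an unadjusted p under 0.05.

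The erythrocyte list had a median of 1.63 and passed camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.522) or fry (adjusted p = 0.0853), and 18 of 100 splits called as many lists. If the shift is real, broken red cells in the diabetic samples are a candidate explanation. The haemolysis index was higher by 1.38 (exact p = 0.177), which does not decide it. The index differed by 2.98 within slide 2 and 0.16 within slide 1, and with it as a covariate the median of the list was 1.00 (adjusted p = 0.113). miR-23a, the reference of the index, was itself higher by 2.19, so the index may understate the red cell signal. Haemolysis and a difference between the groups in red cell miRNAs cannot be told apart here, because the list and the index share miR-451.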

How the results depend on the processing

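Spike-in scaling and the total signal per miRNA were chosen after seeing the data. All 7 list medians stayed above 0 under each alternative that gave lists, but their sizes moved. The diabetes list ranged from 0.33 to 1.66, the liver list from 0.83 to 2.71 and the erythrocyte list from 0.87 to 2.20, each lowest with normexp background. The miR-29 and miR-30 list ranged from 0.35 to 1.32 and the platelet list from 0.20 to 1.14, both lowest with normexp background. The adipose list ranged from 0.19 to 1.45 and the leukocyte list from 0.11 to 1.28, both lowest with the haemolysis covariate. Without diabetic 3 these 2 lists were 0.38 and 0.42. The log2 difference of miR-375 ranged from 0.20 (normexp background) to 1.90, and that of miR-378b from 1.44 to 2.85. In sign, the 6 called miRNAs kept their direction under each alternative that tested them. Outside leave-one-out fits miR-122 passed under 14 alternatives, with log2 differences from 3.22 to 6.22, and miR-193b under 13, miR-139-3p under 10, miR-378b under 9, miR-1892 under 6 and miR-375 under 2. The cause of a lost or added call was not tested, except that fewer arrays or more tests lower power. The number of probes that passed was 14, of miRNAs 6 and of lists 3. These were 2 probes, 4 miRNAs and 4 lists with normexp background, 4, 2 and 4 with the percentile over all probes, 9, 5 and 4 with quantile normalization, 4, 2 and 3 with the authors' unscaled values and the same with spike-in scaling. Without a filter they were 0 probes, 0 miRNAs and 6 lists. The log2 difference of miR-122 stayed at 5.56 (limma adjusted p = 0.0785), and why its call ended was not tested. The 6 include lists that had no set test with the filter. With detection on all arrays they were 8 probes and 3 miRNAs, and no list had 3 members, so lists were not run. They were 0 probes and 0 miRNAs within slide 1 or slide 2, with 2 and 3 lists. Array weights gave 5, 3 and 0, the haemolysis covariate 5, 3 and 1, an estimated correlation 0 lists, fry 2 lists, and the total signal per miRNA 12 miRNAs. Of the 12, 6 were those called above, and the others were miR-483* (1.82), miR-708 (1.72), miR-3065* (1.46), miR-339-3p (1.19), miR-1894-3p (−0.92) and miR-1971 (−1.22).

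With the replicate number as a block, 1 probe, 3 miRNAs and 1 list passed. The numbers do not pair the cats: over 7 same-number pairs the correlation of deviations ranged from −0.63 to 0.67, 5 exceeded 0.1, and 1 diabetic array correlated best with its own number.

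Results near 0 turned. miR-5100 was 0.15 with unscaled values, 0.16 with spike-in scaling, 0.020 with the slide as a block, 0.52 within slide 2 and 0.081 with the replicate block. miR-484 was −0.045 with normexp background and miR-5126 −0.054 with quantile normalization. Within slide 1, miR-133b was −0.043, miR-106b −0.16 and miR-709 −0.20. With the haemolysis covariate miR-106b was −0.079 and miR-709 −0.037, and within slide 2 miR-1224 was 0.010. The haemolysis index difference was 2.98 within slide 2, which passed.

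Leaving out 1 array in turn gave 5 to 17 probes, 3 to 8 miRNAs and 1 to 4 lists. It gave 5 probes without diabetic 3, 5 or 6 or healthy 1, 7 or 8, and 17 without healthy 2 or 3. It gave 3 miRNAs without diabetic 3 or diabetic 5 and 8 without diabetic 1. miR-122, miR-193b and miR-139-3p passed in all 15 fits. miR-378b was lost without diabetic 3 or 5 (adjusted p up to 0.0585), and miR-375 and miR-1892 passed in 4 and 3 fits (adjusted p up to 0.103 in both). The diabetes list passed in 15 fits, the liver list in 12, lost without healthy 3, diabetic 5 or diabetic 6, and the erythrocyte list in 10, lost without diabetic 3, 5 or 6 or healthy 3 or 4. The miR-29 and miR-30 list passed without diabetic 1, diabetic 7, healthy 1 or healthy 6. Single miRNAs gained a call without diabetic 1 (miR-378, miR-339-3p, miR-34a), healthy 2 (miR-5105), healthy 3 (miR-5105, miR-2861) or healthy 6 (miR-1894-3p). The haemolysis index difference ranged from 0.90 to 2.09, the difference in detected probes from 33.9 to 97.7, miR-5100 from −0.30 to 0.14 and miR-1224 from −0.51 to 0.047, the last without healthy 7. Signal over background limits dim miRNAs: 5 of 8 healthy cats had no detected miR-122.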

Other observations

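The tests of miR-1892 without its highest arrays and of detection by chance were chosen only after the results were seen. miR-193b passed (3.40), and miR-193b*, from the other arm of its hairpin, differed by −0.19 (adjusted p = 0.688). The difference between the arms was not tested, and miR-193b was picked for its rise and was undetected in 4 of 8 healthy cats. Outside the test, miR-483* was detected in 5 of 7 diabetic and 1 of 8 healthy cats (exact Fisher p = 0.0406) and was higher by 1.82 (adjusted p = 0.0105) with the total signal per miRNA.

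Other miRNAs outside the test had the same detection counts of 5 of 7 and 1 of 8, with an exact Fisher p of 0.0406 each: miR-365, which shares a genomic cluster with miR-193b, miR-27b, miR-221 and miR-708. Of the 161 detected but untested miRNAs, 96 were detected in more diabetic than healthy cats, 44 in more healthy cats and 21 in the same number of each, of 7 and 8. None passed Fisher's exact test after adjustment (lowest adjusted p = 0.539). With so few detections per miRNA, that test could hardly pass any single one. It also did not test the imbalance of 96 against 44, so it does not decide whether chance gave these counts. That test does not speak against miR-708 (1.72, adjusted p = 0.0200) and miR-483*, which passed on their level with the total signal per miRNA.

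The rises of miR-122, miR-193b, miR-378b, miR-375 and miR-139-3p have several candidate explanations. Haemolysis as the whole cause is argued against by the fit with the haemolysis covariate. The median log2 difference, set by miR-378b with all arrays, kept a share of 0.940 (0.847 to 1.07 when leaving out 1 array). The reference of the index was itself higher in diabetic cats, which limits this. More was lost by miR-122 (5.56, SE 0.909 before and 4.65, SE 0.759 after) and miR-193b (3.40, SE 0.688 before and 2.77, SE 0.608 after). Haemolysis thus stays open for part of the size of these 2. The calls of miR-378b (2.59, SE 0.576 before and 2.43, SE 0.620 after) and miR-375 (1.27, SE 0.328 before and 1.23, SE 0.359 after) ended as the SE grew while the differences moved by less than 1 SE. Array scaling as the whole cause is argued against by a lowest median of 2.20 over 5 other scalings, which miR-378b sets, and by miR-122 and miR-193b passing under all 5. Other calls ended: miR-375 under 5 (lowest difference 1.04, SE 0.359), miR-139-3p under 4 (1.11, SE 0.228 before and at the lowest 0.72, SE 0.277) and miR-378b under 3 (2.27, SE 0.598 with the percentile over all probes). Their differences were smaller with the percentile over all probes or quantile normalization, and larger but with a larger SE with unscaled values or spike-in scaling (miR-139-3p 1.32, SE 0.473). Scaling thus stays open for part of the size of miR-139-3p, which moved by over 1 SE. A general difference in brightness between the slide rows was largely removed by scaling each array before the fit. The hybridisation spike-in difference of 0.068 on the log2 scale (SE 0.251) is therefore no further test of it. The labelling spike-in differed by 0.186 on the log10 scale (exact permutation p = 0.533), with healthy 4 far below the rest, and does not decide this. A row effect on single probes and a biological difference between diabetic and healthy cats, in liver or other tissues, stay open and cannot be told apart, because row and group are the same split.

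The fall of miR-1892 was −1.20 (SE 0.617) under the scaling that brought it nearest 0, which argues against scaling as the whole cause. It passed under 1 of the 5 scalings, and the SE was 0.362 before. Leaving out any 1 array gave −1.56 to −1.22. Without healthy 1 and healthy 8, its highest arrays, the difference was −0.97 (adjusted p = 0.0954), but taking out the highest healthy arrays must shrink it, so this does not decide whether a few arrays carry it.

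Chance was tested with 100 splits of the 15 arrays, the real one included, at a share of 0.05. By that measure it can be excluded for the number of probes, where 1 split gave 14 or more and the highest other gave 13, and for that of miRNAs, where 2 splits gave 6 or more and the highest other gave 13. Both margins are narrow, since leaving out 1 array moved the real counts to 5 to 17 probes and 3 to 8 miRNAs. For the number of lists chance cannot be excluded, as 18 splits gave 3 or more and the highest other gave 6. The split with 13 miRNAs, over 2 times the real count, put 4 diabetic cats in its group of 7, and its groups differed by 5.32 on the log2 scale in miR-451. It was picked for its count and was not compared with other splits, so the source of its calls is untested.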
